A study of Homo sapiens with 31 samples.

How the data were processed

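The samples were MDAMB231_1833, MDAMB231, MDAMB468, HCC1937 and MCF7 breast cancer cells and MRC5 fibroblasts, in mono-culture or sorted after coculture, on 31 arrays. The groups, replicate numbers, siRNA states and partners were taken from the labels, and 0 columns of the table were left unmapped. The deposited table held 32321 probe sets as log2 values between 2.45 and 14.2. The authors name RMA and affy 1.38.1 in their processing notes, without the order of steps. The array quartiles lay close together, as quantile normalization leaves them, and the labels do not say which arrays were normalized together or which chip definition was used. No further normalization was done.

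Probe sets were named with the naming table of the array, and symbols were updated by gene identifier. Of the 32321 probe sets 19158 had 1 symbol and were used, 1388 had several and 11775 were not listed. For each of the 18404 genes the probe set with the highest mean over all arrays stood for the gene, and 637 genes had several. STAT1 is not analysed here, and no check of the knockdown on its target was made. The array build is not stated, so no coordinates are given. The 2 technical arrays of MRC5 mono-culture replicate 2 (Pearson correlation 0.9936 across genes, against 0.994 between replicates 1 and 2) were averaged. MRC5 mono-culture replicate 3, labelled control siRNA, was used with the other mono-cultures.

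The 9 comparisons were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with a Benjamini-Hochberg adjusted p under 0.05 over all 18404 genes, no fold minimum and no filter. The 10 MDAMB231_1833 arrays were fitted together, so that groups of 1 or 2 arrays shared the spread, and so were the 12 MRC5 values. The MRC5 test over partners averages the 5 partners with a spread from replicate arrays, not between partners. The coculture effect in MDAMB231_1833 weighted the pair without siRNA by its 1 replicate and the control siRNA pairs by their 2. Over lines, the unit was the line, with 1 log ratio of coculture to mono-culture for each of 5 lines and an intercept test. Lines and partners with 1 array have values and no test. The replicate numbers were checked for pairing by correlating group-centred values of samples that share a number. All of these correlations were above 0, from 0.18 to 0.48, so pairs were formed by number, and a fit with the number as a block was an alternative. Tests on simulated data with 200 changed genes of 18404 recovered 74% to 100% of genes changed by 1 log2 and 100% of those changed by 2 log2 over the 9 comparisons. They gave 10 to 20 false calls per comparison (20 of 235 for coculture in MDAMB231_1833), and up to 2 unchanged lists were called. The simulated noise was independent between genes and arrays, so these tests do not cover carry-over or correlated values.

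In total 20 gene lists with 385 entries, 356 of them measured, were written before the data were examined, covering interferon (IRDS_core, interferon_stimulated, interferon_gamma_type), sensing, antigen presentation, Notch, exosome_biogenesis, NF-kB and inflammation, matrix proteases, cell cycle, markers of fibroblasts, carcinoma cells and leukocytes, TGF-beta and contraction, hypoxia_glycolysis, stress of unfolded proteins and amino acids, cholesterol_synthesis, p53 targets, immediate-early and mesenchymal genes. They were tested with camera at a preset correlation of 0.01, and with an estimated correlation as an alternative, with adjustment over the 20 lists. The adjusted p of a list is from the preset correlation unless an estimated correlation is named. In single pairs a list's median was set against 10000 random lists matched on mean expression. The named genes followed a rule written at the same time. It took STAT1 and the other IRDS_core genes, the 8 largest rises and 8 largest falls among passing genes that moved the same way in every pair, the 3 lowest raw p values in each direction where none passed, the 4 members with the largest change of each list, and the 5 largest rises and falls in single pairs among genes at or above the median level. Not every gene the rule allows is named.

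The share of RNA from the other cell type was estimated after the data were seen. It used fibroblast and carcinoma markers at least 3 log2 apart between the mono-cultures, 13 to 17 fibroblast markers and 4 to 15 carcinoma markers per coculture, whose median ratios between the sorted fractions of a coculture give both shares. It assumes that the sorted cells do not themselves change these markers. An alternative took the shares out of both fractions on the linear scale, with a floor at 4 log2. A gene with a lower ratio between the fractions than the markers is set to this floor. Its change of sign then follows from the method, and its size is not interpreted.

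The alternatives chosen before the data were examined were the replicate block, a fit of the compared groups alone, the lowest 40% of genes left out, quantile normalization repeated, the mean of all probe sets of a gene, a trended and robust variance, each array, value or line left out, and for the lines other weights. Chosen afterwards were the removal of the other cell type's share, a count of genes that moved away from the other fraction, a fit without the mono-culture that held fibroblast transcripts, and the repeats for single pairs. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.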

Results

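Gene expression was measured on 31 Affymetrix Human Gene 1.0 ST arrays of breast cancer cells and of MRC5 lung fibroblasts, grown alone (mono-culture) or mixed 1:1 (coculture) and then separated by fluorescence-activated sorting on a dye. The cancer lines were MDAMB231_1833, a bone-metastatic derivative of MDAMB231, then MDAMB231 itself, MDAMB468 and HCC1937, which lack the estrogen receptor, and MCF7, which carries it. Of the 18 cancer arrays, 10 held MDAMB231_1833: 1 mono-culture and 1 coculture without siRNA, and 2 arrays for each combination of culture with control siRNA or with siRNA against STAT1, the transcription factor of the interferon response. The siRNA dose was 15 nM. Each of the other 4 lines had 1 mono-culture and 1 coculture array. The 13 MRC5 arrays gave 12 values, since 2 technical arrays of mono-culture replicate 2 were averaged: 3 for mono-culture, 3 for coculture with MDAMB231_1833 without or with control siRNA, 2 for coculture with MDAMB231_1833 labelled STAT1 siRNA, and 1 for each other partner. The deposited values were log2 intensities whose array medians lay between 6.94 and 7.08, and they gave 18404 genes. The number of arrays limits the precision of every value. Changes are log2 fold changes ± SE unless a fold is given. STAT1 itself was not analysed here.

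The first comparison asked what coculture with MRC5 changed in MDAMB231_1833, with 3 cocultures against 3 mono-cultures. Interferon-induced genes rose most consistently among the fixed lists. The antiviral effector MX1 rose 20.9-fold (4.39 ± 0.36), the RNA-degradation activator OAS1 18.8-fold (4.23 ± 0.35) and the viral RNA binder IFIT1 by 3.83 ± 0.31, each in 3 of 3 pairs. All 6 measured genes of the interferon-related DNA damage resistance signature (IRDS_core) rose, the others being IFI44 by 2.87 ± 0.25, IFIT3 by 1.76 ± 0.21 and ISG15 by 1.67 ± 0.22. Their median change was 3.35, and the same 6 passed adjusted over the list alone. Of 41 further interferon-stimulated genes 40 rose over all genes tested and 41 adjusted over the list alone, among them IFI44L (5.84 ± 0.51), MX2 (4.58 ± 0.43) and OAS2 (3.86 ± 0.24). The lists were called with a preset correlation (adjusted p = 8.3e-14 for IRDS_core and 3.4e-60 for interferon_stimulated) and not with an estimated correlation (adjusted p = 0.069 for both). In the same sorted cells, fibroblast markers were higher too, by a median of 3.08. OAS1 and ISG15 among the IRDS_core genes, and 8 of the 40 risen interferon-stimulated genes, were at a higher level in the sorted cancer cells than in the MRC5 cells sorted from the same culture in all 3 cocultures.

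Genes of the interferon-gamma, NF-kB, sensing and antigen-presentation lists rose in part, in the same arrays in which fibroblast markers were higher by a median of 3.08. The T-cell attracting chemokine CXCL10 rose 30.5-fold (4.93 ± 0.38), and 6 of 16 interferon-gamma-type genes rose, with CXCL11 (1.87 ± 0.20) and GBP2 (1.02 ± 0.16) among them, or 8 adjusted over the list alone. Of 26 NF-kB target and inflammatory genes 5 rose and 1 fell, including rises of the chemokines CCL5 (3.31 ± 0.44) and CCL2 (2.03 ± 0.12) and of the cytokine IL6 (1.49 ± 0.31), and the counts were the same adjusted over the list alone. The viral RNA sensors IFIH1 (2.42 ± 0.14) and RIGI (1.07 ± 0.11) were among 5 of 14 sensing genes that rose, and 1 fell, against 7 and 2 adjusted over the list alone. Of 12 antigen-presentation genes 3 rose, including B2M (1.13 ± 0.14) and the peptide transporter TAP1 (0.90 ± 0.10), or 6 adjusted over the list alone. With the estimated MRC5 share taken out, CCL5 (-0.57) and IL6 (-1.39) changed sign, and no gene of the NF-kB or interferon-gamma lists rose. With an estimated correlation the adjusted p was 0.069 for the interferon-gamma, sensing and antigen-presentation lists and 0.18 for the NF-kB list.

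Genes that MRC5 cells express at high levels were among the largest rises. The matrix proteins POSTN (6.73 ± 0.90), SPARC (6.61 ± 1.07), DCN (5.94 ± 0.99) and COL1A2 (4.95 ± 0.68) rose in 3 of 3 pairs, as did the growth-factor binding protein IGFBP5 (5.10 ± 0.78) and the cadherin PCDH18 (4.89 ± 0.54). In the 3 mono-cultures DCN (4.71 to 4.74 log2), POSTN (4.55 to 4.74), PCDH18 (5.2 to 5.33) and CXCL10 (4.13 to 4.77) lay below the lower quartile of each array (5.34 to 5.40), near background. Their changes are thus lower bounds of the difference between the samples. They are not lower bounds of a change in the cancer cells, since the sorted cells also held MRC5 RNA by estimate. Of 22 fibroblast markers 20 rose, or 21 adjusted over the list alone (adjusted p = 1.2e-27, and 0.069 with an estimated correlation). None of the 20 stood higher in the sorted cancer cells than in the sorted MRC5 cells in all 3 cocultures. The median log2 ratio of fibroblast markers between the sorted cancer cells and the sorted MRC5 cells was -1.52, -1.23 and -2.23 in the 3 cocultures, which corresponds to a share of MRC5 RNA of 26.2%, 18.7% and 11.1%. Moving with these markers, the collagen COL4A1 (2.42 ± 0.22), the matrix protein TGFBI (2.94 ± 0.54), the gelatinase MMP2 (3.86 ± 0.50), its inhibitor TIMP1 (1.22 ± 0.17), the cadherin CDH2 (1.59 ± 0.19) and fibronectin, FN1 (1.88 ± 0.37), rose. By list, 6 of 17 TGF-beta and contractile genes, 4 of 17 matrix protease genes and 5 of 13 mesenchymal genes rose, against 13, 8 and 7 adjusted over the list alone. The adjusted p with an estimated correlation was 0.13, 0.14 and 0.069. The contractile genes ACTA2 (2.83 ± 0.68) and TAGLN (2.48 ± 0.59) did not pass (adjusted p = 0.056 and 0.054), but passed with the replicate number as a block. With the estimated MRC5 share taken out, PCDH18 (-1.28), MMP2 (-2.01), CDH2 (-1.16), COL4A1 (-2.27), ACTA2 (-3.13) and TAGLN (-2.28) changed sign. For a gene with a lower ratio than the markers this follows from the subtraction, so the sizes are not interpreted.

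**Figure D1:**
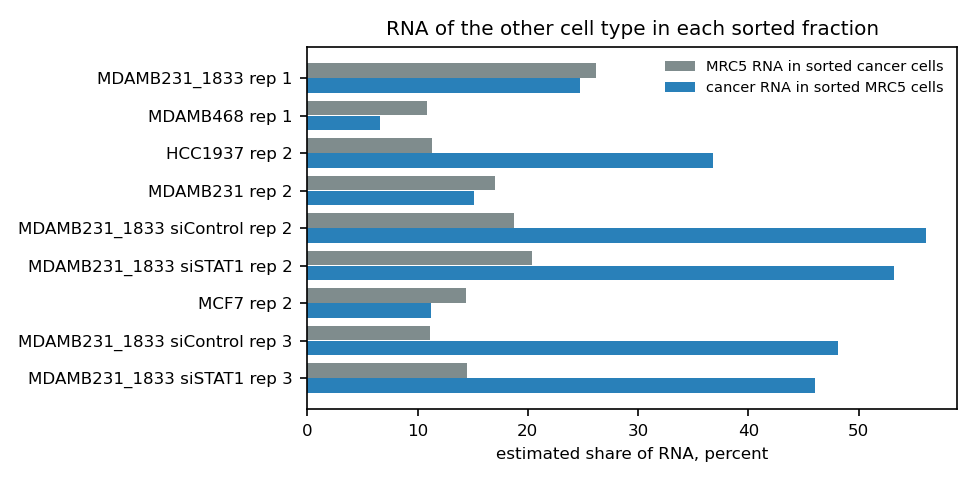
Estimated share of RNA (percent, x axis) from MRC5 cells in each sorted cancer sample (grey bars) and from cancer cells in each sorted MRC5 sample (blue bars), for the 9 cocultures (y axis), from marker genes of the other cell type. The grey bars lie between 10.9% and 26.2% and the blue bars between 6.6% and 56.1%.

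Among the smaller groups, 10 of 32 cell-cycle genes fell, such as the replication factor CDC6 (-0.88 ± 0.19), and 29 fell adjusted over the list alone (median -0.43; adjusted p = 8e-16, and 0.13 with an estimated correlation), while with the estimated MRC5 share taken out the median was -0.14 and 0 fell. The receptor NOTCH3 (1.16 ± 0.15) and the Notch target HEY1 (0.48 ± 0.10) were the 2 of 18 Notch genes that rose, against 4 adjusted over the list alone (adjusted p = 3.1e-05, and 0.15 with an estimated correlation). NOTCH3 was higher in the sorted MRC5 cells. The transcription factors FOS (1.13 ± 0.18) and FOSB (0.79 ± 0.11) were among 3 of 16 immediate-early genes that rose, or 7 adjusted over the list alone (adjusted p = 2.2e-06, and 0.069 with an estimated correlation). With the share taken out NOTCH3 (-2.55), FOS (-0.01) and FAS (-2.46) changed sign. FAS, a death receptor (0.80 ± 0.16), was among 2 of 16 p53 targets that rose, in the full test and adjusted over the list alone (adjusted p = 0.019, and 0.42 with an estimated correlation). No member passed over all genes in the exosome_biogenesis list (14 genes, median -0.09, adjusted p = 0.59) or in hypoxia_glycolysis (17 genes, median -0.13, adjusted p = 0.31). None passed in cholesterol_synthesis (16 genes, median -0.23, adjusted p = 0.00032, and 0.24 with an estimated correlation). The same was true of the unfolded-protein and amino-acid stress list (16 genes, median -0.36, adjusted p = 0.00014, and 0.28 with an estimated correlation). Adjusted over the list alone, 0, 0, 4 and 10 genes of these lists fell, and 1 gene of the last rose. Of 18 epithelial carcinoma markers KRT7 alone passed, and it fell (-0.72 ± 0.13; list median -0.03, adjusted p = 0.66), while 1 rose and 2 fell adjusted over the list alone. Of 9 leukocyte markers CD68, a lysosomal protein, alone rose (0.50 ± 0.09; list median 0.07, adjusted p = 0.062), or 2 adjusted over the list alone. The largest falls among genes that moved the same way in all pairs were in MS4A4A (-1.30 ± 0.21), OR5P2 (-1.27 ± 0.29), ZNF114 (-1.24 ± 0.17) and the cysteine-synthesis enzyme CTH (-1.02 ± 0.19).

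Over all genes, limma called 784 in this comparison, 568 higher and 216 lower in coculture. With the replicate number as a block 1694 passed. Of the 568 risen genes 496 (87.3%) stood higher in the sorted MRC5 cells in all 3 cocultures and 30 (5.3%) stood higher in the sorted cancer cells, against 24.1% and 26.2% of all genes. Of the 216 fallen genes 170 (78.7%) stood higher in the sorted cancer cells, where dilution by MRC5 RNA would also lower them. The count moved between 255 and 3043 with 1 array left out, and it was highest without coculture replicate 2 with control siRNA. With the estimated MRC5 share taken out 472 passed, 197 higher and 275 lower.

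The next question was which of these changes other breast cancer lines shared. In single pairs, without replicates and without a test, MDAMB231 stood nearest to its derivative. Its IRDS_core median was 2.19, against 3.22 to 3.48 in the 3 MDAMB231_1833 pairs, and IFI44L was higher by 5.12. In HCC1937 the IRDS_core median was 1.00 and IFI44L was higher by 2.83, next to CCL2 (2.85) and the gelatinase MMP9 (2.53). In MCF7 the IRDS_core median was -0.20, and in MDAMB468 it was -0.59, at percentile 0 of 10000 random lists matched on mean expression. Fibroblast markers were higher in coculture in every line, with medians of 2.63 in MDAMB231, 0.91 in HCC1937, 2.65 in MCF7 and 1.5 in MDAMB468. The HCC1937 mono-culture itself held DCN at 9.37 log2, against 4.85 in the MDAMB231 mono-culture. Among the largest single-pair ratios were DCN (6.33) and SPARC (6.01) in MDAMB231, SPARC (5.71), DCN (5.50) and the protease inhibitor SERPINE2 (5.26) in MCF7, and the contractile gene ACTA2 (4.92), SPARC (4.08) and the collagen crosslinker LOX (3.87) in MDAMB468. The mono-culture level of DCN lay below the array's lower quartile in MDAMB231 (4.85 against 5.33) and MCF7 (5.09 against 5.37). These DCN ratios start near background and are not exact. The lowest ratios included SLCO4C1 in MDAMB231 (-1.85, or -0.65 with the mean of its probe sets), RASGRP1 (-1.73) in MCF7, PEG10 (-1.22) in HCC1937, and CRISP3 (-2.49) and RGS2 (-1.51) in MDAMB468. Across 18404 genes, which are not independent replicates, the log ratios of MDAMB231_1833 and MDAMB231 correlated at 0.79, and the other 9 pairs of lines at 0.29 to 0.52.

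**Figure D2:**
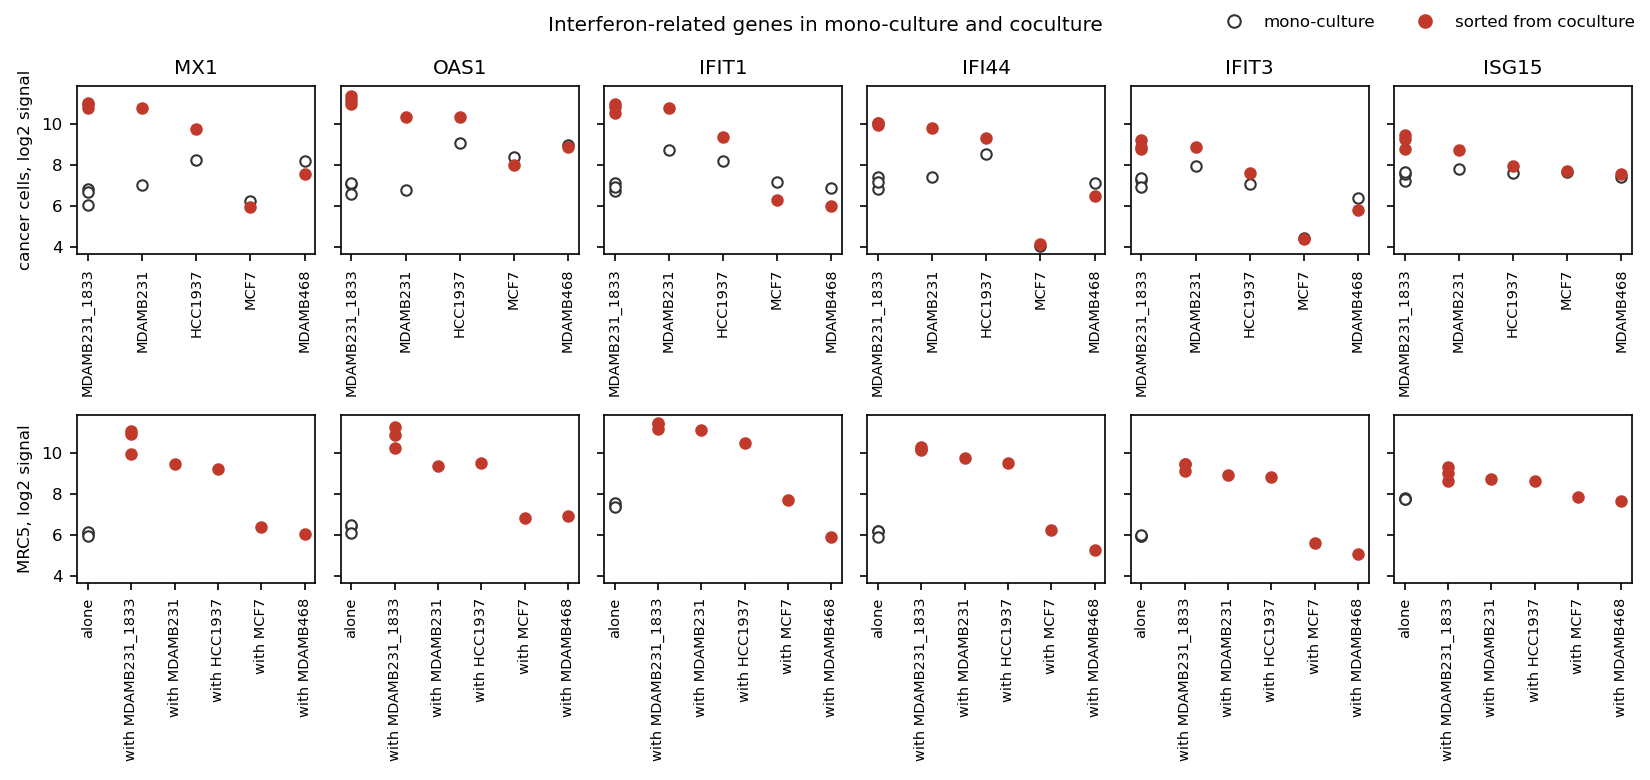
Log2 signal (y axis) of the 6 measured IRDS_core genes in cancer cells (top, by line) and MRC5 cells (bottom, by partner), 1 point per array or averaged sample, in mono-culture (open) and after coculture (filled), without STAT1 siRNA. MX1 was 4.39 higher in cocultured MDAMB231_1833 than in mono-culture, while the IRDS_core median of MDAMB468 was 0.59 lower, the change being -0.59.

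Tested over the 5 lines as units, matrix genes were among the largest rises. SPARC (4.63 ± 0.77), POSTN (4.25 ± 0.70), the proteoglycan VCAN (3.88 ± 0.40), COL6A3 (3.51 ± 0.45), COL1A2 (3.45 ± 0.52), MMP2 (3.11 ± 0.36), the membrane protein TMEM47 (3.24 ± 0.49) and the complement protease C1S (3.09 ± 0.50) rose in 5 of 5 lines. Of 22 fibroblast markers 12 rose, or 20 adjusted over the list alone (adjusted p = 0.17 with an estimated correlation), and 7 of 17 TGF-beta and contractile genes rose, including TAGLN (1.84 ± 0.23), COL4A1 (1.79 ± 0.23) and TGFBI (1.97 ± 0.28), or 10 adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). The chemokine CCL2 (2.18 ± 0.29), CDH2 (1.32 ± 0.15), CD68 (0.57 ± 0.06) and the ERK phosphatase DUSP6 (0.68 ± 0.11) also rose. With the estimated MRC5 share taken out, VCAN (-1.60), MMP2 (-0.49), TMEM47 (-2.13), C1S (-1.51), CCL2 (-0.57), TAGLN (-2.58), CDH2 (-2.09) and COL4A1 (-2) changed sign. In these cocultures an estimated 10.9% to 26.2% of the RNA of the sorted cancer cells was MRC5 RNA, if the cells do not change the fibroblast markers. For MDAMB468, the lowest, carry-over could not be told apart from expression by the cells. Falls were small, led by PGCKA1 (-0.68 ± 0.11), PIGW (-0.55 ± 0.07), MCOLN3 (-0.54 ± 0.09) and ZNF704 (-0.50 ± 0.08). None of the 6 IRDS_core or 41 interferon-stimulated genes passed over all genes, with OAS1 at 1.70 ± 0.68 (adjusted p = 0.25) and MX1 at 1.74 ± 0.74 (adjusted p = 0.27), each higher in 3 of 5 lines, and 0 and 2 passed adjusted over the list alone. The list medians were 1.09 and 0.66 (adjusted p = 0.0016 and 1.3e-14 with the preset correlation, and 0.33 and 0.31 with an estimated correlation). Of 16 immediate-early genes 3 rose and 12 did so adjusted over the list alone (median 0.47; adjusted p = 0.099 with an estimated correlation). In all, limma called 162 genes, 117 higher and 45 lower, against 531 (222 higher, 309 lower) with the estimated MRC5 share taken out and 1251 (592 higher, 659 lower) with 7 pairs at equal weight. No gene passed with MDAMB231_1833 and MDAMB231 averaged, where 2495 had a raw p under 0.05, or with a trended, robust variance, and 3 to 111 passed with 1 line left out. Ignoring the pairs, without a replicate block, 887 passed.

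**Figure D3:**
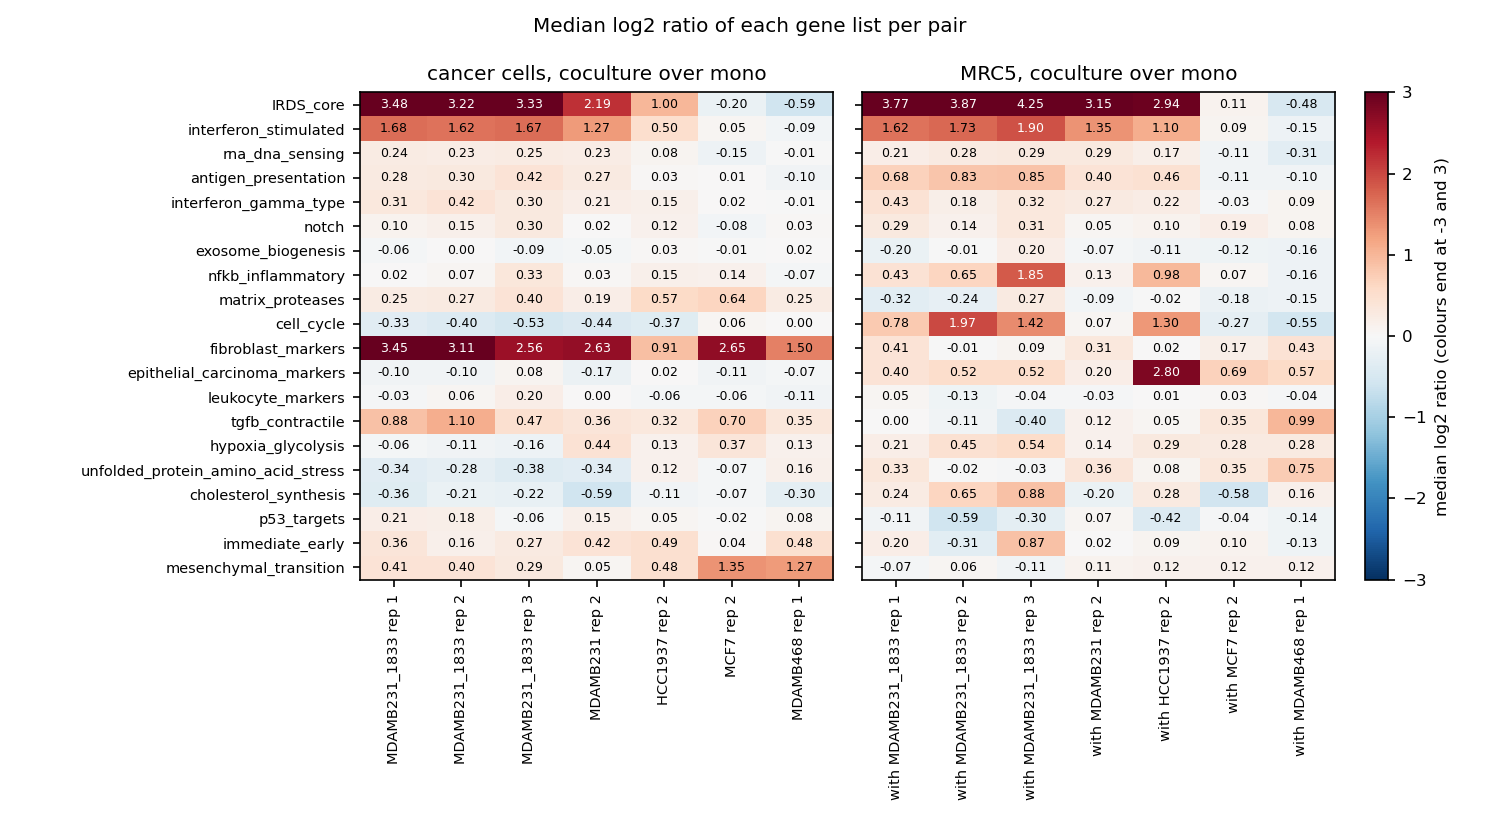
Median log2 ratio of coculture over mono-culture (colour and printed value) for the 20 gene lists (rows) in each pair (columns), for cancer cells (left) and MRC5 cells (right), without STAT1 siRNA. IRDS_core medians run from -0.59 to 3.48 in cancer cells and from -0.48 to 4.25 in MRC5 cells.

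STAT1 siRNA in MDAMB231_1833 mono-culture was compared with control siRNA, 2 arrays each. No gene passed. The lowest raw p values belonged to the cytokine IL24 (1.67 ± 0.25), the proton-pump subunit ATP6V0D2 (1.57 ± 0.23) and SDR16C5 (0.77 ± 0.11) among genes at higher levels, and to CLMN (-1.03 ± 0.12), the glycolytic enzyme ALDOC (-1.10 ± 0.17) and TCEA3 (-0.76 ± 0.11) among those at lower levels. OAS1 (0.42 ± 0.43) and MX1 (0.48 ± 0.44) differed by about their SE, and MX1 changed sign without STAT1 siRNA replicate 2 (-0.13). That mono-culture held fibroblast transcripts, with DCN at 9.71 log2 against 4.71 to 4.75 in the other 4 MDAMB231_1833 mono-cultures, and its fibroblast markers were higher than theirs by a median of 1.56. The cell-cycle list had a median of -0.30 (adjusted p = 2.4e-15, and 0.37 with an estimated correlation), and the unfolded-protein and amino-acid stress list one of 0.34 (adjusted p = 5.7e-07, and 0.37 with an estimated correlation), with 8 of its 16 genes higher adjusted over the list alone. Limma called 0 genes, with 1171 at a raw p under 0.05, and 32 without STAT1 siRNA replicate 3. The fit with the replicate number as a block called 0 as well.

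In coculture, interferon genes lay lower with STAT1 siRNA, but no gene passed with 2 arrays each. OAS1 was 2.27-fold lower (-1.19 ± 0.43, adjusted p = 0.60), MX1 1.82-fold lower (-0.86 ± 0.44), IFI44 1.74-fold lower (-0.80 ± 0.30) and IFIT1 1.55-fold lower (-0.63 ± 0.38), each in 2 of 2 pairs. The medians were -0.71 for IRDS_core and -0.40 for interferon_stimulated, and no member passed adjusted over the list alone. The 2 pairs lay apart, at -1.09 and -0.27 for IRDS_core and at -0.63 and -0.17 for interferon_stimulated. Both lists were called with the preset correlation (adjusted p = 0.0039 and 1.4e-13) and not with an estimated correlation (adjusted p = 0.58 for both). Fibroblast markers differed by a median of 0.06 between these groups. The lowest raw p values were those of the long non-coding RNA UCA1 (1.42 ± 0.20), ARB2BP (0.98 ± 0.14) and the lipid kinase DGKD (0.79 ± 0.13) on the higher side, and TMEM163 (-0.99 ± 0.12), the carbonic anhydrase CA12 (-0.87 ± 0.13) and CLMN (-0.75 ± 0.12) on the lower side. Limma called 0 genes, also with the replicate number as a block, with 1494 at a raw p under 0.05. Without control siRNA coculture replicate 2, 744 passed, a fit in which the lone control array is assumed to vary like the other groups.

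**Figure D4:**
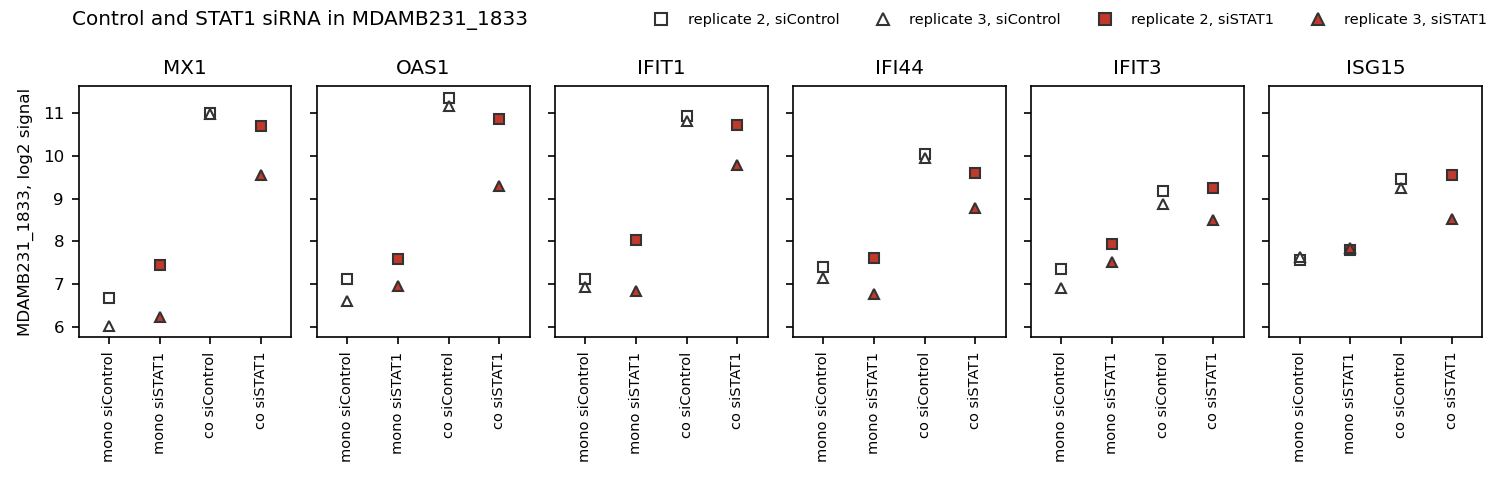
Log2 signal (y axis) of the 6 measured IRDS_core genes in each MDAMB231_1833 array with control siRNA (open) or STAT1 siRNA (filled), in mono-culture and coculture, with squares for replicate 2 and triangles for replicate 3. In coculture OAS1 lay 1.19 log2 below control, the change being -1.19, while in mono-culture it lay 0.42 above.

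With STAT1 siRNA present, coculture was still followed by higher interferon genes in MDAMB231_1833. The sorted cancer cells held an estimated 20.4% and 14.5% of MRC5 RNA in replicates 2 and 3. CXCL10 (4.72 ± 0.47), IFI44L (4.03 ± 0.62), MX2 (3.55 ± 0.53), MX1 (3.28 ± 0.44), OAS2 (3.14 ± 0.29), IFIT1 (2.81 ± 0.38), OAS1 (2.80 ± 0.43) and IFI44 (2.01 ± 0.30) rose in 2 of 2 pairs, while IFIT3 (1.15 ± 0.26) and ISG15 (1.22 ± 0.27) did not pass (adjusted p = 0.12 and 0.11), but passed with the replicate number as a block. Of 41 interferon-stimulated genes 17 rose, or 40 adjusted over the list alone, and 4 of 6 IRDS_core genes rose, or 6 adjusted over the list alone (adjusted p = 0.067 for both lists with an estimated correlation). Of 22 fibroblast markers 3 rose, or 20 adjusted over the list alone, with a median of 2.15 (adjusted p = 0.067 with an estimated correlation). The growth factor HGF (3.85 ± 0.55), the peptidase MME (3.79 ± 0.25) and the ligand WNT5A (3.16 ± 0.53) rose as well but changed sign with the estimated MRC5 share taken out (-1.96, -2.27 and -1.44), and ANKFN1 (-0.77 ± 0.11) was the single gene that fell. The difference between this coculture effect and that with control siRNA was -1.60 ± 0.61 for OAS1, -1.34 ± 0.63 for MX1, -1.03 ± 0.53 for IFIT1 and -1.80 for IFI44L, none of which passed (adjusted p = 0.94 for OAS1). The median difference was -0.89 for IRDS_core and -0.50 for interferon_stimulated (adjusted p = 0.40 for both with an estimated correlation). The fibroblast markers had a median of -0.61 (adjusted p = 0.0011, and 0.59 with an estimated correlation), but -1.38 and 0.25 in the 2 pairs, against -0.94 and -0.82 for IRDS_core and -0.63 and -0.37 for interferon_stimulated. The STAT1 siRNA mono-culture of replicate 2, which held fibroblast transcripts, had an IRDS_core median level of 7.70, against 6.89 to 7.24 in the other 4 MDAMB231_1833 mono-cultures. Among other genes, the lowest raw p values of this difference included LOC399975 (0.88 ± 0.21) and the adrenergic receptor ADRB3 (-0.82 ± 0.18). The coculture effect with STAT1 siRNA covered 128 genes, 127 higher and 1 lower, or 331 with the replicate number as a block, 4 in a fit of its own 4 arrays, 19 to 208 with 1 array left out, and 185 (56 higher, 129 lower) with the MRC5 share taken out. For the difference between the effects limma called 0 genes, also with the replicate number as a block, with 381 at a raw p under 0.05, and 59 or 21 without control siRNA coculture replicate 2 or STAT1 siRNA mono-culture replicate 3.

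In MRC5 cells, coculture with MDAMB231_1833 was followed by a rise of the same gene families. The siRNA labels were not balanced in this comparison. Replicate 1 had no siRNA in either culture, and replicate 3 had control siRNA in both. Replicate 2 set a coculture labelled control siRNA against a mono-culture without siRNA. In replicate 1, IFI44L was higher by 6.16, CXCL10 by 4.69 and OAS2 by 4.61. In that pair 320 genes were at least 1 log2 higher, against 841 and 785 in replicates 2 and 3. IFI44L rose 71.0-fold (6.15 ± 0.12), CXCL10 63.9-fold (6.0 ± 0.51), OAS2 41.4-fold (5.37 ± 0.27) and the chemokine CCL5 29.5-fold (4.88 ± 0.16), in 3 of 3 pairs, and the value of CXCL10 is a lower bound, as its mono-culture levels (4.74 to 5.30 log2) lay below the arrays' lower quartiles. All 6 IRDS_core genes rose, with MX1 at 4.58 ± 0.25, OAS1 at 4.43 ± 0.28, IFI44 at 4.10 ± 0.12, IFIT1 at 3.90 ± 0.12, IFIT3 at 3.39 ± 0.13 and ISG15 at 1.22 ± 0.17. Of 41 interferon-stimulated genes 39 rose, among them IFIT2 (4.36 ± 0.16), or 40 adjusted over the list alone. The adjusted p with an estimated correlation was 0.071 for IRDS_core and 0.058 for interferon_stimulated. Cancer RNA made up an estimated 24.7%, 56.1% and 48.1% of the RNA in these sorted MRC5 cells. With these shares taken out, 13 of 22 fibroblast markers rose and 0 fell, with a median of 0.98. Either the shares are too high or the MRC5 cells raised these markers, against the assumption of the estimate. Of the risen genes, 3 of the IRDS_core genes and 18 of the 39 interferon-stimulated genes stood higher in the sorted MRC5 cells than in the sorted cancer cells in all 3 cocultures. The Notch targets HES1 (2.38 ± 0.13) and HEY1 (1.12 ± 0.21), the ligand JAG1 (1.81 ± 0.18) and the receptor NOTCH3 (1.11 ± 0.10) were among 6 of 18 Notch genes that rose, in the full test and adjusted over the list alone, and 5 of the 6 stood higher in the sorted MRC5 cells (adjusted p = 0.13 with an estimated correlation). Of 26 NF-kB target and inflammatory genes 12 rose, including CXCL8 (3.6 ± 0.51) and IL6 (3.10 ± 0.32), or 15 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation), and 9 of the 12 stood higher in the sorted MRC5 cells. Of 12 antigen-presentation genes 10 rose, or 11 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation), and 3 of the 10 stood higher in the sorted MRC5 cells. With the estimated cancer share taken out 1 of the 12 rose, while the list's median was 0.69, against 0.74 before.

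Cell-cycle and epithelial genes rose in the same MRC5 arrays. Of 32 cell-cycle genes 25 rose, such as the kinase CDK1 (2.63 ± 0.34), or 26 adjusted over the list alone (median 1.42; adjusted p = 0.16 with an estimated correlation). Of 18 epithelial carcinoma markers 8 rose, including the keratins KRT19 (3.45 ± 0.28) and KRT8 (2.46 ± 0.26), or 10 adjusted over the list alone (adjusted p = 0.091 with an estimated correlation). None of the 25 or of the 8 stood higher in the sorted MRC5 cells than in the sorted cancer cells in all 3 cocultures. The protease inhibitor CST1 (5.25 ± 0.62), SPANXB1 (5.00 ± 0.32) and the epithelial transcription factor EHF (4.88 ± 0.31) were among the largest rises. With the estimated cancer share taken out, CDK1 (-2.23), KRT19 (-0.79), KRT8 (-1.30) and CST1 (-1.54) changed sign. The largest falls were in the growth factor PDGFD (-3.19 ± 0.37), the potassium channel KCNJ2 (-3.18 ± 0.26), the integrin ITGA8 (-3.04 ± 0.28), SLC7A14 (-3.03 ± 0.49), the transcription inhibitor ID2 (-3.01 ± 0.22), the angiogenic factor ANGPT1 (-2.67 ± 0.51), ITGB8 (-2.36 ± 0.29) and FGL2 (-2.32 ± 0.37). Limma called 2086 genes, 1203 higher and 883 lower, and 3393 with the replicate number as a block, or 519 (254 higher, 265 lower) with the estimated cancer share taken out. Of the 1203, 893 (74.2%) stood higher in the sorted cancer cells in all 3 cocultures and 175 (14.5%) in the sorted MRC5 cells, against 26.2% and 24.1% of all genes. Of the 883 fallen genes 537 (60.8%) stood higher in the sorted MRC5 cells, where dilution by cancer RNA would also lower them. With 1 value left out 889 to 2938 genes passed.

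On average over the 5 partner lines, interferon-stimulated and epithelial genes rose in MRC5. This test takes its spread from replicate MRC5 arrays and not from the partners, so it speaks for the mean of these 5 partners and not for others, unlike the test over cancer lines. IFI44L (3.84 ± 0.10), the death ligand TNFSF10 (2.52 ± 0.14) and OAS1 (2.33 ± 0.24) rose in 7 of 7 cocultures. MX1 (2.29 ± 0.22) and IFIT1 (1.87 ± 0.10) rose and were higher in 6 of 7. Of 6 IRDS_core genes 5 rose, and ISG15 (0.60 ± 0.15) passed only adjusted over the list alone. Of 41 interferon-stimulated genes 24 rose, or 34 adjusted over the list alone (adjusted p = 0.064 and 0.052 for these lists with an estimated correlation). Epithelial genes rose beside them, with MAL2 (3.56 ± 0.20), EHF (2.96 ± 0.27), KRT8 (2.52 ± 0.22), the adhesion molecule EPCAM (2.36 ± 0.25) and the desmosome protein DSP (2.29 ± 0.26). Of 18 epithelial markers 14 rose, or 17 adjusted over the list alone, and this list was also called with an estimated correlation (adjusted p = 0.024). With the estimated cancer share taken out EHF (-0.27), EPCAM (-1.19) and DSP (-0.73) changed sign. Cancer RNA made up an estimated 6.6% to 56.1% of the RNA in the sorted MRC5 cells. HES1 (2.11 ± 0.11) and NOTCH3 (0.78 ± 0.09) were among 3 of 18 Notch genes that rose, or 6 adjusted over the list alone (adjusted p = 0.15 with an estimated correlation), and CCL5 (2.72 ± 0.14) and IL6 (2.13 ± 0.28) among 5 of 26 NF-kB target and inflammatory genes, or 9 adjusted over the list alone (adjusted p = 0.27 with an estimated correlation). The matrix-degrading protease ADAMTS5 (-2.71 ± 0.58), ITGA8 (-2.61 ± 0.24), SLC7A14 (-2.51 ± 0.43), KCNJ2 (-2.39 ± 0.22), SEMA6A (-2.32 ± 0.17), TSPAN12 (-2.24 ± 0.27), the growth factor FGF9 (-2.13 ± 0.34) and ITGB8 (-2.08 ± 0.25) fell in 7 of 7 cocultures. Limma called 560 genes, 342 higher and 218 lower, and 857 with the replicate number as a block, or 318 (136 higher, 182 lower) with the estimated cancer share taken out. With 1 value left out 158 to 1001 passed.

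The single partners, each with 1 array, differed in their values, and these differences were not tested. The IRDS_core median of MRC5 was 3.15 with MDAMB231 and 2.94 with HCC1937, 0.11 with MCF7 and -0.48 with MDAMB468, next to 3.77 to 4.25 with MDAMB231_1833. With MDAMB231, IFI44L (5.70) and CCL5 (4.05) were highest and SEMA6A (-2.05) lowest. With HCC1937, MAL2 (6.93), the protease inhibitor SLPI (5.30) and IFI44L (5.02) were among the highest ratios and KCNJ2 (-2.83) the lowest, at an estimated 36.8% of cancer RNA. With MCF7, the estrogen-induced gene TFF1 (4.33), KRT8 (3.27) and the luminal transcription factor GATA3 (3.11) were high and ADAMTS5 (-2.39) was low, at an estimated 11.2% of cancer RNA. With MDAMB468, the oxidase NOX4 (3.30) and the sulfatase SULF1 (3.16) were high and ADAMTS5 (-4.42) and the pattern-recognition gene PTX3 (-3.65) were low, at an estimated 6.6% of cancer RNA.

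The last comparison set MRC5 cells from cocultures labelled STAT1 siRNA against those labelled control siRNA, 2 arrays each. Interferon genes lay slightly lower, with OAS1 at -0.69 ± 0.28, MX1 at -0.51 ± 0.12, IFI44 at -0.47 ± 0.14 and IFIT1 at -0.41 ± 0.12, and no gene passed. The medians were -0.44 for IRDS_core and -0.31 for interferon_stimulated, with 3 and 0 genes lower adjusted over the list alone (adjusted p = 0.17 and 0.15 with an estimated correlation). The estimated share of cancer RNA was 56.1% and 48.1% with control siRNA and 53.2% and 46.0% with STAT1 siRNA. The lowest raw p values were those of MAL2 (1.01 ± 0.21), GPRC5B (0.73 ± 0.14) and ATP6V0D2 (0.65 ± 0.12) on the higher side, and the ectonucleotidase ENPP1 (-1.11 ± 0.18), CST2 (-0.99 ± 0.18) and LINC01711 (-0.66 ± 0.11) on the lower side. With the estimated cancer share taken out ATP6V0D2 (0), CST2 (0) and LINC01711 (0.16) lost their direction. Limma called 0 genes, also with the replicate number as a block, with 259 at a raw p under 0.05, and 33 (2 higher, 31 lower) with the cancer share taken out. The labels do not say whether the siRNA reached the fibroblasts.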

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

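The tests on the interferon genes of MDAMB231_1833, the test of a STAT1 siRNA effect on fibroblast transcripts, and the limit that leaves out list medians close to those of random lists were chosen only after the results were seen.

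The most visible pattern is the appearance of fibroblast transcripts in cancer cells sorted from coculture and of carcinoma transcripts in MRC5 cells from the same cultures. If MRC5 RNA had been carried into the cancer fraction, all genes abundant in MRC5 mono-culture alone should share the cancer-to-MRC5 ratio of the fibroblast markers. Within 1 log2 of that ratio lay 77.7% of 318 such genes in the MDAMB468 coculture, the lowest, and 84.5% to 99.5% in the other 8, against the 80% set in advance for each. For cancer RNA in the MRC5 fraction the lowest was 79% of 248 genes, again in MDAMB468, and 85.2% to 100% elsewhere. The marker ratios in MDAMB468 (-3.1 and -3.77) and MCF7 (-2.63 and -2.94) were near the 3 log2 gap by which these genes were chosen. Genes without carry-over could thus lie within 1 log2 there as well, so the test decides little in these 2 cocultures. Carry-over past the dye sort, which is meant to part the cell types, by whole cells, doublets or shed RNA, may account for most of these transcripts, while in MDAMB468 it cannot be told apart from expression by the cells themselves, since the values lie just under the limit.

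The second pattern is the rise of interferon-stimulated genes in MDAMB231_1833. The median of observed levels minus those expected from MRC5 RNA at the share given by the markers was 0.82, 1.03 and 1.13 log2 in the 3 cocultures. In these, 40 or 41 of 41 genes lay above. The expected level used the sorted MRC5 cells, which held cancer RNA themselves. It is therefore too low for genes higher in MRC5, and such differences are overstated in every line. With both shares taken out the list's median change was 1.45, and 30 of 41 genes rose while 1 fell. Together this argues against carry-over as the whole cause. Transfection with siRNA is argued against by the pair without siRNA, where the list's median change was 1.68. A response that depends on the line stays open, because each other line had 1 coculture: the median of observed minus expected levels was 0.99 in MDAMB231, 0.43 in HCC1937, -0.06 in MDAMB468 and -0.13 in MCF7. In MDAMB231_1833 with STAT1 siRNA it was 0.83 and 0.51 in replicates 2 and 3. The expected levels of HCC1937 and of STAT1 siRNA replicate 2 start from mono-cultures that themselves held fibroblast transcripts. Their values of 0.43 and 0.83 can therefore not be compared directly with the others. It is a hypothesis found and tested on the same data that MDAMB231_1833 cells may themselves raise interferon genes in coculture.

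The third pattern concerns the MDAMB231_1833 mono-culture with STAT1 siRNA, replicate 2, which held COL1A1 at 10.08, DCN at 9.71 and COL1A2 at 10.15 log2, against 7.64 to 8.13, 4.71 to 4.75 and 6.64 to 6.97 in the other 4. An effect of the siRNA is argued against by replicate 3 with the same siRNA. Its fibroblast markers had a median level of 6.59, against 6.65 to 6.79 in the MDAMB231_1833 mono-cultures without STAT1 siRNA. Relative to the other mono-cultures they lay at a median of -0.35. That reference includes replicate 2, and the mono-cultures without STAT1 siRNA lay at -0.47 to -0.36 on the same measure. For MRC5 RNA mixed into the sample, at a share of 11.2% by the markers, 69.8% of 212 MRC5-enriched genes lay within 1 log2 of the level predicted, 97.2% lay higher than in the other mono-cultures, and the median of observed minus expected was -0.80. This cannot be told apart from another source of fibroblast transcripts, because the genes lay higher as a set but below the predicted level.

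Other values stood out because single pairs moved against the 3 MDAMB231_1833 pairs, and these differences were not tested. In cancer cells they were the medians of IRDS_core in MDAMB468 (-0.59, against 3.22 to 3.48), interferon_stimulated in MDAMB468 (-0.09, against 1.62 to 1.68), sensing genes in MCF7 (-0.15, against 0.23 to 0.25), cell-cycle genes in MCF7 (0.06, against -0.53 to -0.33), and the unfolded-protein and amino-acid stress list in MDAMB468 (0.16) and HCC1937 (0.12), against -0.38 to -0.28. In MRC5 they were IRDS_core (-0.48, against 3.77 to 4.25), interferon_stimulated (-0.15, against 1.62 to 1.90), sensing (-0.31, against 0.21 to 0.29) and NF-kB genes (-0.16, against 0.43 to 1.85) with MDAMB468, cell-cycle genes with MDAMB468 (-0.55) and MCF7 (-0.27), against 0.78 to 1.97, and cholesterol_synthesis with MDAMB231 (-0.20) and MCF7 (-0.58), against 0.24 to 0.88.

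The interaction of STAT1 siRNA with culture, tested with camera at the preset correlation, gave adjusted p values under 0.05 for 12 lists, with medians of -0.89 for IRDS_core, -0.50 for interferon_stimulated, -0.17 for sensing, -0.11 for interferon_gamma_type, -0.18 for Notch and for NF-kB genes, 0.28 for cell-cycle genes, -0.61 for fibroblast markers, -0.14 for leukocyte markers and for immediate-early genes, 0.11 for hypoxia_glycolysis and 0.22 for cholesterol_synthesis. For the fibroblast markers the 2 replicates disagreed in sign (-1.38 and 0.25), and the STAT1 siRNA mono-culture of replicate 2 held fibroblast transcripts (1.56 above the other mono-cultures). With an estimated correlation none of the 12 was called (adjusted p = 0.40 to 0.67).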

How the results depend on the processing

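The removal of the other cell type's share, the count of genes that moved away from the other fraction, the fit without MDAMB231_1833 mono-culture STAT1 siRNA replicate 2 in the first comparison and the repeats for single pairs were chosen only after the results were seen.

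Of 2241 values for 168 gene results, 1892 kept direction and side of the threshold, 287 lost the call, 29 gained it and 33 reversed or fell to 0. Of the 287, 160 came from leaving out 1 array, value or line and 48 from removing the carried-over share. For single pairs 78 of 80 values moved little, none reversed, and SLCO4C1 in MDAMB231 went from -1.85 to -0.65 with the mean of its probe sets.

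With the replicate number as a block the counts were 1694 (coculture in MDAMB231_1833), 331 (the same with STAT1 siRNA), 3393 (MRC5 with MDAMB231_1833) and 857 (MRC5 over partners). Across lines, ignoring the pairs (no replicate block) gave 887, 7 pairs with equal weight 1251, MDAMB231_1833 and MDAMB231 averaged 0 (limma, 2495 at a raw p under 0.05), and trend and robust variance 0 (3091). With STAT1 siRNA, a fit of its own groups gave 4 genes and leaving out dim genes 78. The cause was not tested. Repeated quantile normalization and the mean of probe sets kept all 9 counts within 1.5 times. With an estimated correlation, the epithelial markers in MRC5 over partners were the single list over the 9 comparisons that kept a call (adjusted p = 0.024).

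Leaving out 1 array, a lone array being assumed to vary like the other groups, gave these ranges, each with the arrays that moved the count over 1.5 times. Coculture in MDAMB231_1833 gave 255 to 3043: 305 without either array of replicate 1, 255 and 3043 without control siRNA replicate 2 in mono-culture and in coculture, and 318 without control siRNA mono-culture replicate 3. STAT1 siRNA gave 0 to 32 in mono-culture (32 without its replicate 3), 0 to 744 in coculture (744 without control siRNA replicate 2) and 0 to 59 for the interaction (59 without control siRNA coculture replicate 2, 21 without STAT1 siRNA mono-culture replicate 3). Coculture with STAT1 siRNA gave 19 to 208: 208 and 50 without mono-culture replicates 2 and 3, 19 without coculture replicate 2. The lines gave 3 to 111: 3 without MDAMB231_1833, 7 without MDAMB231, 82 without HCC1937, 22 without MCF7. MRC5 with MDAMB231_1833 gave 889 to 2938: 1224 and 889 without mono-culture replicates 1 and 2, 1111 and 1000 without control siRNA coculture replicates 2 and 3. MRC5 over partners gave 158 to 1001: 1001 without MDAMB231_1833 replicate 1, 356 without HCC1937, 250, 158 and 336 without mono-culture replicates 1, 2 and 3. MX1 under STAT1 siRNA in mono-culture lay between -0.13 (without STAT1 siRNA replicate 2) and 1.09. The MRC5 comparison by partner siRNA stayed at 0.

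With the carried-over share taken out the counts were 472 (197 higher, 275 lower, 222 shared with the 784) in MDAMB231_1833, 185 (56 higher, 129 lower, 52 shared with the 128) with STAT1 siRNA, 1 (STAT1 siRNA in coculture), 531 (222 higher, 309 lower) over the lines, 519 (254 higher, 265 lower) and 318 (136 higher, 182 lower) in MRC5 with MDAMB231_1833 and over partners, and 33 (2 higher, 31 lower; MRC5 by partner siRNA), so more genes were lower than higher in each of these but the interaction, which stayed at 0 (limma, 641 at a raw p under 0.05). Counting only genes that moved away from the other fraction left 40 in MDAMB231_1833 and 244 in MRC5. Reversed in MDAMB231_1833 were CCL5 (-0.57), IL6 (-1.39), PCDH18 (-1.28), MMP2 (-2.01), CDH2 (-1.16), COL4A1 (-2.27), NOTCH3 (-2.55), FOS (-0.01), ACTA2 (-3.13), TAGLN (-2.28) and FAS (-2.46), and with STAT1 siRNA HGF (-1.96), MME (-2.27) and WNT5A (-1.44). Across lines VCAN (-1.60), MMP2 (-0.49), TMEM47 (-2.13), C1S (-1.51), CCL2 (-0.57), TAGLN (-2.58), CDH2 (-2.09) and COL4A1 (-2) reversed. In MRC5, CST1 (-1.54), KRT19 (-0.79), KRT8 (-1.30) and CDK1 (-2.23) with MDAMB231_1833, and EHF (-0.27), EPCAM (-1.19) and DSP (-0.73) over partners, reversed. By partner siRNA LINC01711 (0.16) reversed, and ATP6V0D2 (0) and CST2 (0) were left with no change. By its construction this subtraction takes a gene with a lower ratio than the markers below its mono-culture level. In MRC5 with MDAMB231_1833 it left fibroblast markers higher by a median of 0.98, so the cancer shares there may be too high. Signal near the background limits small changes of dim genes.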

Other observations

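The tests named in this part were chosen before the results were seen, except the counts with the other cell type's share taken out, the genes picked for their ratio between the sorted fractions, and the splits drawn within replicate numbers.

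Of the 568 genes that rose in MDAMB231_1833, 30 stood higher in the sorted cancer cells than in the sorted MRC5 cells in all 3 cocultures, where MRC5 RNA alone would place them lower. They include genes named in the report, such as OAS1 and ISG15, and, chosen after their values were seen, the interferon signal component IRF9 (1.60 ± 0.14), the DNA sensor AIM2 (1.39 ± 0.15), the virus tether BST2 (1.24 ± 0.13) and the nucleotide hydrolase SAMHD1 (1.25 ± 0.13). On the falling side 10 genes stood lower in the sorted cancer cells, among them the cytokine IL11 (-0.69 ± 0.13) and the adhesion scaffold NEDD9 (-0.55 ± 0.12). With the MRC5 share taken out, the 6 IRDS_core genes rose by a median of 3.10 and 30 of 41 interferon-stimulated genes rose while 1 fell. The median of fibroblast markers was -0.32, but the share was estimated from markers of this list. Their loss of rise thus follows in large part from the method and is no separate test. Other lists lost calls, with medians before and after: interferon_gamma_type went from 6 risen to 0 (1 fell; 0.39 and 0.11), NF-kB from 5 to 0 (2 fell; 0.11 and -0.15), TGF-beta and contractile from 6 to 0 (4 fell; 0.70 and -0.98), mesenchymal from 5 to 0 (0.35 and -0.09), p53 from 2 to 0 (4 fell; 0.09 and -0.30) and Notch from 2 to 0 (0.16 and 0.04). Fibroblast markers went from 20 risen to 2 (3 fell), matrix proteases from 4 to 2 (0.25 and -0.08), immediate-early genes from 3 to 1 (1 fell; 0.29 and 0.02) and sensing genes from 5 to 4 (0.20 and 0.11), while antigen presentation stayed at 3. The cell-cycle list went from 10 fallen to 0 (-0.43 and -0.14), and in the unfolded-protein and amino-acid stress list 6 fell (-0.36 and -0.67). In MRC5 with the cancer share taken out, 5 IRDS_core, 30 interferon-stimulated, 5 Notch and 10 NF-kB genes rose, against 6, 39, 6 and 12 before, and their medians were 4.12, 2.01, 0.34 and 1.03, against 4, 1.73, 0.22 and 0.95. Antigen presentation went from 10 risen to 1 and interferon_gamma_type from 7 to 3, but their medians were 0.69 and 0.66, against 0.74 and 0.34, so these lists lost calls while their medians stayed near or above those before. Fibroblast markers went from 4 risen to 13 (0.23 and 0.98).

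Cell-cycle genes rose in MRC5 sorted from coculture with MDAMB231_1833 by a median of 1.42, and cancer RNA carried into that fraction may be the source. With the cancer share taken out the median was -1.76 over 32 genes, below the mono-culture level, so the size is not interpreted. Epithelial markers went from a median of 0.44 to -0.29, but the cancer share was estimated from markers of this list, so their drop follows in part from the method. No test of fibroblast proliferation was made.

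Other splits of the samples were counted for the comparisons with at least 3 samples per group. For MDAMB231_1833 and MRC5 they used fits of the compared groups alone, with the siRNA state as a covariate in MDAMB231_1833. The real counts given here therefore differ from the 784, 2086 and 560 of the main fits. For coculture in MDAMB231_1833 the real split of the 6 arrays gave 627 genes and the highest of the other splits 112, 1 of 10 splits being as large, and the other splits that part all 3 pairs gave at most 0. For MRC5 with MDAMB231_1833 the values were 1715 and 0, again 1 of 10. Over the lines they were 162 and 0, 1 of 16. These splits are too few for a share under 0.05. For MRC5 over partners 2 of 100 splits, the real one included, were as large as the real 464, and 2 of 100 were when labels were drawn within replicate numbers. This share is under 0.05, but the highest other labellings gave 1160 and 961 genes, more than the real one. Chance is therefore not called excluded, since the samples may not be exchangeable. The split with 1160 genes put MRC5 mono-culture replicates 1 and 2 and the coculture with MDAMB231 together as mono-culture, and it points to a structure of the samples whose cause was not tested, while the next highest of the same draw gave 105.

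The HCC1937 mono-culture held DCN at 9.37, COL1A2 at 9.93 and COL1A1 at 9.89 log2, at a median of 9.8% of the MRC5 mono-culture over 5 matrix genes, against 15.5% in the MDAMB231_1833 mono-culture with STAT1 siRNA, replicate 2, and 1.4% to 3.3% in the other 7 mono-cultures of cancer lines. Of the 22 fibroblast markers 13 to 17 and of the 18 carcinoma markers 4 to 15 were at least 3 log2 apart between the mono-cultures of a pair. The others lay closer together between the mono-cultures and were not used for the shares.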
